A study of Homo sapiens and Mus musculus with 16 samples.

How the data were processed

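The samples were 16 libraries of total RNA, 8 from MDA-MB-231, a human triple-negative breast cancer line, and 8 from CT26, a mouse colon carcinoma line. In each line 4 libraries came from cells with wild type PD-L1 and 4 from cells in which the gene had been knocked out with lentiviral CRISPR, per the labels' protocols. Whether the knockout cells were a pool or a clone, and whether the 4 libraries of a group came from separate cultures, is not given in the sources used here. The p-values then measure only the spread between these libraries, which may be technical.

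Per the submitters' processing notes, base calls were converted with bcl2fastq 2.18, reads were aligned with STAR 2.5.4a, and Cufflinks 2.2.1 and Cuffdiff were used, with genome builds hg38 and mm10. The annotation release, the use of strand and the Cuffdiff settings are not given in the sources used here. Each line had its own deposited table, with a value in FPKM (fragments per kilobase of transcript per 1e6 mapped fragments) for each gene and library, the authors' group means in FPKM, the authors' test statistic as a score, and the authors' p-value and q-value. The tables were normalized apart from each other, so levels were never compared between lines. A deposited column of fold changes held text in many cells and was not used. Of the symbols, 27 in each table had been turned into calendar dates. All 27 human ones were restored by Ensembl ID, and the mouse ones are known here by Ensembl ID. The authors' status column marked 13 genes in MDA-MB-231 and 210 in CT26 as having too much data to estimate, and all of these were listed at 0 in every library. They include abundant genes such as Rpl13 and Aprt, so these zeros are failed estimates, and the genes were not tested.

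The depth was read from the low FPKM values, which were taken to be whole multiples of what 1 read is worth. Ratios of such values between libraries gave the depth of each library relative to wild type replicate 1 of its line. Genes below 0.5 FPKM in every library and above 0 in at least 2 were then checked. Of their values above 0, 75.9% in MDA-MB-231 and 75.8% in CT26 were whole multiples within 2%. The smallest value of each gene, scaled for depth, served as its 1 read and so passes by construction. No baseline was set for these shares, so they are a weak check. For MDA-MB-231 a fit on transcript length over 1862 genes with a single transcript in GENCODE 29 gave depths in M fragments (M, 1e6) on the authors' scale, and 71.7% of those genes lay within 2% of the line. The line was refitted to the genes closest to it, so the share near it is no independent check. No mouse annotation was used, so CT26 depths are relative. Shallower libraries carry more counting error at low FPKM, and this mostly concerns the MDA-MB-231 knockout.

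Values were analysed as log2(FPKM + 1), so fold changes understate the change of low genes. Genes with FPKM of at least 1 in at least 4 of a line's 8 libraries were tested, 14450 in MDA-MB-231 and 11342 in CT26. Knockout was compared with wild type in limma 3.58.1 under R 4.3.3, with a mean-variance trend and the group as the only term. The tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The targeted gene also had an exact permutation test over the 70 assignments of its 8 values. A list of 29 gene groups was fixed before the data were examined, as were the tests and the rule for naming genes. Lists with at least 5 tested members were compared with all other genes by camera, with a preset correlation between genes of 0.01 and, beside it, a correlation estimated from the data. Genes of both lines were paired by symbol. Counts of genes changed in both lines were set against those of independent lists with a one-sided Fisher's exact test, and responses were called different between lines when the difference exceeded 2-fold in limma's treat. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for depths and plots.

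The named genes were the targeted gene, the 10 largest rises and the 10 largest falls per line among genes past the threshold, with a mean of at least 5 FPKM in the higher group and no overlap between the groups, and up to 4 members per list with the smallest adjusted p. For both lines together they were the first 10 changes in the same direction and the first 5 in opposite directions, ranked by the smaller of the 2 absolute log2 fold changes. Symbols of some forms, such as LOC, LINC, MIR, Gm and Rik, were passed over. How many of the allowed list members the text describes was decided after their values were seen. Members of near-identical families, such as the HLA, H2, MAGEA, SAA and haemoglobin genes, can share reads, and overlapping or antisense genes cannot be told apart where strand was not used, so their values are less certain.

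The fits were tested on simulated data with the real means and spreads and 200 changed genes. With a log2 change of 0.5, 59% of changed genes were recovered in MDA-MB-231 and 81% in CT26. With a log2 change of 1, 90% and 94% were recovered, with 5 and 10 false calls. For the difference between lines, 93.5% of genes that differed by log2 2 were recovered over 8588 genes, with 0 false calls. The changed genes were drawn from those above about 5 FPKM in the wild type, and at higher levels still for the difference between lines. The recoveries therefore do not hold for low genes. The simulation changed far fewer genes than the data and held no chromosome or scaling shifts, so its false calls say little about the real calls. The alternatives were other pseudocounts, filters and scalings, the replicate number as a block, a robust fit, each library left out in turn, centring on 20 Mb windows, chromosomes left out, and protein-coding genes only. The count models planned for whole reads were not run because the values are FPKM.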

Results

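RNA was sequenced from MDA-MB-231 and CT26 cells, with 4 PD-L1 wild type and 4 PD-L1 knockout libraries in each line. PD-L1, encoded by CD274 in human and Cd274 in mouse, is the cell-surface ligand of the T cell receptor PD-1. The design asks which transcripts differ in the tumour cells themselves when the gene is disrupted. In MDA-MB-231 the wild type libraries held 17.7 to 22.7 M fragments (M, 1e6) on the authors' scale and the knockout libraries 9.55 to 14.6 M. In CT26 the depth relative to wild type replicate 1 was 0.799 to 1.14 in the wild type and 0.926 to 2.49 in the knockout. Genes at 1 FPKM or more numbered 14111 to 14269 in the wild type and 13952 to 14001 in the knockout of MDA-MB-231, and 11151 to 11311 and 11321 to 11348 in CT26.

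The targeted transcript fell in the CT26 knockout and did not pass the test in the MDA-MB-231 knockout. Cd274 (ENSMUSG00000016496, mm10 chromosome 19, 29367455 to 29388095 in the deposited table) went from 1.41 ± 0.127 to 0.526 ± 0.0552 FPKM (SD, n = 4 per group), which left 37.2% of the wild type mean. Its log2 fold change was -0.66 with SE 0.077, limma adjusted p = 1.42e-04, and the exact permutation p of 0.0286 was the smallest that 70 assignments allow. After centring on 20 Mb windows it was -0.38 (limma adjusted p = 0.00490), since the median gene of its window fell too. The pseudocount compresses the change of so low a gene, so the window's share of the fall cannot be read from this. At this low level the log2 fold change of Cd274 also moved with the pseudocount, to -1.27 at 0.1 and -0.21 at 5. CD274 (ENSG00000120217, hg38 chromosome 9, 5450503 to 5470566 in GENCODE 29) went from 12.2 ± 0.670 to 10.6 ± 1.91 FPKM (SD, n = 4 per group), or 86.6% of the wild type mean. Its log2 fold change was -0.20 with SE 0.12, limma adjusted p = 0.166 and exact permutation p = 0.229. The 4 knockout libraries of MDA-MB-231 read 9.93, 11.6, 8.19 and 12.5 FPKM for CD274, against 11.2 to 12.8 in the wild type. After upper-quartile scaling the log2 fold change was -0.40 and limma's adjusted p = 0.0157, and after quantile normalization they were -0.32 and 0.0425. Over all alternatives the adjusted p of CD274 ran from 0.0157 to 0.382, the highest without knockout replicate 3. A CRISPR indel need not lower its own transcript, so the transcript level alone does not check the labels. In the authors' deposited table the q-value was 0.360 for CD274 and 2.14e-04 for Cd274.

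**Figure D1:**
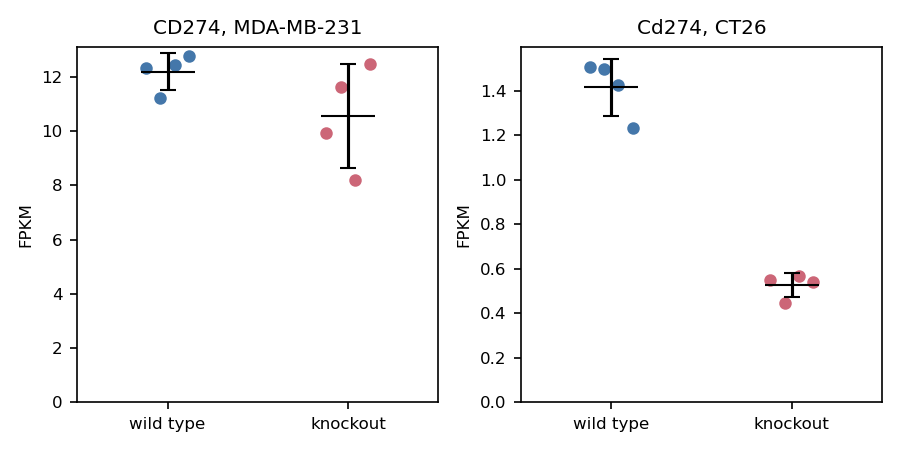
FPKM of CD274 in MDA-MB-231 (left) and Cd274 in CT26 (right) for each library (points), with the group mean (line) and SD (bars, n = 4). The groups do not overlap in CT26, where the means are 1.41 and 0.526 FPKM, and overlap in MDA-MB-231, where they are 12.2 and 10.6 FPKM.

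In MDA-MB-231 the knockout libraries had lower levels of most tested MHC class II genes, NF-kappaB target genes and interferon-stimulated genes. CD74, the class II invariant chain, went from 1134 ± 33.9 to 1.36 ± 0.593 FPKM (SD, n = 4 per group), and HLA-DRA, a class II chain, from 382 ± 15.01 to 0.407 ± 0.234 FPKM. The interferon-stimulated gene IFI27 went from 311 ± 13.6 to 0.185 ± 0.128 FPKM, the calcium-binding protein gene S100A4 from 1347 ± 75.7 to 9.08 ± 2.22 FPKM and the cytokine gene IL6 from 224 ± 14.4 to 0.965 ± 0.418 FPKM. In the other direction KISS1, known as a metastasis suppressor gene, went from 0.654 ± 0.401 to 244 ± 12.9 FPKM, and PHGDH, which encodes the first enzyme of serine synthesis, from 1.35 ± 0.844 to 57.7 ± 7.40 FPKM. In all, 9860 of 14450 genes (68.2%) changed in limma at an adjusted p below 0.05, 6149 higher and 3711 lower in the knockout, with 1671 and 1438 of them by at least 2-fold on the log2(FPKM + 1) scale.

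The 10 largest falls also held HLA-DRB1 (log2 fold change -7.96, SE 0.06, adjusted p = 1.83e-11), HLA-DPA1 (log2 fold change -7.15), the protease inhibitor gene SERPINA1 (-6.79), the acute-phase gene SAA2 (-6.77) and the complement gene C3 (-6.67). The 10 largest rises were led by KISS1 (log2 fold change 7.24, SE 0.16, adjusted p = 2.90e-09) and the collagen chaperone gene FKBP10 (log2 fold change 6.18, SE 0.13, adjusted p = 2.43e-09). The others were LCP1, an actin-bundling protein gene of blood cells (log2 fold change 6.10), the calcium channel subunit gene CACNA2D4 (5.82) and the cancer-testis genes MAGEA6 (5.43) and MAGEB2 (4.999), with AC244153.1 (5.10), PHGDH (4.70), CD96 (4.63) and LY6K (4.57). Of the 14450 genes, 62.7% had groups that did not overlap, where chance gives 2.86%.

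Among antigen presentation genes of MDA-MB-231, 19 of 21 tested MHC class I members fell and 0 rose, and 15 of 16 class II members fell and 1 rose. HLA-C went from 458 ± 18.2 to 27.0 ± 2.12 FPKM (SD, n = 4 per group), HLA-E from 188 ± 3.29 to 56.9 ± 1.97 FPKM and TAPBP, the peptide-loading factor tapasin, from 127 ± 2.85 to 24.9 ± 1.98 FPKM. The class II gene HLA-DPB1 went from 82.8 ± 2.70 to 0.0163 ± 0.0326 FPKM. The list medians, relative to the median of all genes, were -1.36 for class I (camera adjusted p = 1.28e-09, and adjusted p = 0.00836 with an estimated correlation) and -4.88 for class II (3.73e-10, and adjusted p = 0.00684 with an estimated correlation).

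Interferon-stimulated genes of MDA-MB-231 fell in 30 of 37 tested members and rose in 3, with a median of -1.62 relative to all genes. OASL went from 21.3 ± 0.245 to 0.409 ± 0.176 FPKM, the ubiquitin-like modifier gene ISG15 from 246 ± 4.80 to 24.6 ± 3.23 FPKM and BST2, which encodes tetherin, from 125 ± 3.91 to 0.556 ± 0.418 FPKM. The camera adjusted p was 1.74e-10, and adjusted p = 0.0186 with an estimated correlation. Of 19 interferon pathway components 11 fell and 2 rose (camera adjusted p = 0.00697, and adjusted p = 0.0626 with an estimated correlation). The feedback inhibitor SOCS1 went from 8.20 ± 0.881 to 0.151 ± 0.0851 FPKM, while its relative SOCS3 went from 8.94 ± 0.888 to 25.2 ± 1.004 FPKM.

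NF-kappaB target genes fell in 18 of 22 members and rose in 2, and other cytokines, chemokines and growth factors fell in 18 of 25 and rose in 4. The chemokine genes CXCL8 and CXCL1 went from 62.9 ± 4.12 to 1.19 ± 0.218 FPKM and from 43.4 ± 4.08 to 0.627 ± 0.256 FPKM, and the apoptosis inhibitor gene BIRC3 from 43.4 ± 0.902 to 4.02 ± 0.326 FPKM. The growth factor genes AREG, CSF1 and BMP4 had log2 fold changes of -4.01, -4.34 and -3.59, and the cytokine gene IL32 of -5.29. The camera adjusted p was 6.15e-10 for the first list and 2.55e-06 for the second, and with an estimated correlation adjusted p = 0.00684 and adjusted p = 0.00836. Of 13 immune checkpoint genes other than CD274, 10 fell and 3 rose (camera adjusted p = 0.00227, and adjusted p = 0.0626 with an estimated correlation). CD47, a signal against phagocytosis, went from 141 ± 7.91 to 55.8 ± 3.60 FPKM, TNFSF9 from 6.31 ± 0.652 to 0.871 ± 0.116 FPKM, NECTIN2 from 92.8 ± 3.19 to 46.6 ± 3.07 FPKM and LGALS9 from 3.29 ± 0.443 to 0.187 ± 0.222 FPKM.

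Extracellular matrix and integrin genes of MDA-MB-231 fell in 21 of 25 members and rose in 3 (camera adjusted p = 1.96e-07, and adjusted p = 0.00836 with an estimated correlation), among them COL5A1 from 142 ± 3.29 to 9.69 ± 1.02 FPKM and THBS1 from 403 ± 24.7 to 82.7 ± 3.49 FPKM. Epithelial markers fell in 12 of 14 and rose in 2 (camera adjusted p = 4.90e-06, and adjusted p = 0.0103 with an estimated correlation). Named members were the keratin genes KRT7 from 1370.3 ± 36.8 to 37.8 ± 1.45 FPKM and KRT19 from 319.8 ± 7.08 to 7.74 ± 0.171 FPKM. Glycolysis and hypoxia genes fell in 20 of 32 and rose in 10 (camera adjusted p = 2.64e-04, and adjusted p = 0.118 with an estimated correlation). Examples were EGLN3 and P4HA2 at log2 fold changes of -4.39 and -3.45. Replication-dependent histone genes fell in 7 of 10 and rose in 1 (camera adjusted p = 0.0356, and adjusted p = 0.134 with an estimated correlation). HIST1H2BD was at -1.08, and HIST1H2BK rose, at 0.56. After centring on 20 Mb windows the histone list median relative to all genes moved from -0.68 to -0.27, with 4 lower and 2 higher (camera adjusted p = 0.752). Of 13 mitochondrially encoded genes 7 fell and 0 rose (camera adjusted p = 0.0115, and adjusted p = 0.531 with an estimated correlation), led by MT-ND6 at -1.85 and MT-ND5 at -1.62, which lie on opposite strands of the same genome.

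Cytosolic ribosomal protein genes of MDA-MB-231 rose in 29 of 34 members and fell in 0 (camera adjusted p = 2.46e-06, and adjusted p = 0.409 with an estimated correlation). Members included RPL4 and RPL13 at log2 fold changes of 1.30 and 1.32. After upper-quartile scaling 25 of them rose and 4 fell. Nuclear-encoded respiratory chain genes rose in 19 of 28 and fell in 3 (camera adjusted p = 0.00754, and adjusted p = 0.457 with an estimated correlation). Named members were COX4I1 at 1.32 and NDUFA9 at 1.21. Cholesterol genes rose in 17 of 24 and fell in 2 (camera adjusted p = 0.00349, and adjusted p = 0.140 with an estimated correlation). The regulator SREBF2 rose from 11.6 ± 0.777 to 42.2 ± 0.409 FPKM, and the sterol isomerase gene EBP fell from 123 ± 3.57 to 44.4 ± 3.32 FPKM. Fatty acid synthesis genes rose in 9 of 14 and fell in 2 (camera adjusted p = 0.0371, and adjusted p = 0.143 with an estimated correlation). Among them were the desaturase genes SCD from 13.0 ± 0.634 to 145 ± 8.76 FPKM and FADS2 from 36.2 ± 2.06 to 214 ± 14.9 FPKM. G1/S and DNA replication genes rose in 18 of 26 and fell in 3 (camera adjusted p = 0.0106, and adjusted p = 0.137 with an estimated correlation). Members included GINS2 at 1.62 and PCNA at 0.77. After quantile normalization the camera adjusted p was 0.0534 for fatty acid genes, 0.121 for G1/S genes, 0.128 for respiratory chain genes (0.0671 after window centring) and 0.0660 for histone genes, and without knockout replicate 2 it was 0.0590 for fatty acid genes.

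The other lists of MDA-MB-231 did not pass camera, with adjusted p from 0.0625 to 0.900. Some passed under other settings at the preset correlation, the only one tried there. In the main fit with an estimated correlation, camera gave adjusted p = 0.673 for trafficking partners, 0.556 for G2/M genes and 0.457 for heat shock genes. It gave 0.308 for leukocyte markers and 0.142 for mesenchymal genes. With no filter, trafficking partners (camera adjusted p = 0.0397), G2/M genes (0.00321) and heat shock genes (0.0109) passed as higher and leukocyte markers (0.0301) as lower. Heat shock genes also passed as higher after window centring (camera adjusted p = 0.00827), and mesenchymal genes as lower with the stricter filter (0.00852). Members rose and fell in 14 and 5 of 26 PD-L1 trafficking partners, 7 and 9 of 16 mesenchymal genes, 8 and 10 of 20 TGF-beta and YAP targets, 17 and 4 of 26 G2/M genes, and 5 and 7 of 19 p53 targets. The counts were 11 and 8 of 27 stress response genes, 10 and 3 of 14 heat shock genes, 9 and 6 of 19 NRF2 genes, and 7 and 11 of 21 immediate early genes. They were 1 and 3 of 5 leukocyte markers, 0 and 2 of 5 fibroblast and endothelial markers, and 3 and 1 of 5 neural and melanocyte markers. After upper-quartile scaling the trafficking partners read 9 and 9 and the G2/M genes 10 and 6. After quantile normalization they read 10 and 10, and 9 and 5. Among immediate early genes IER3 and IER5 had log2 fold changes of -1.51 and -1.32, and DUSP5 and DUSP1 of 1.97 and 1.77. Adjusted over the list alone, the counts differed for MHC class I, where 1 member rose, for matrix and integrin genes, where 22 fell, and for mitochondrially encoded genes, where 6 fell.

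The median log2 fold change over all MDA-MB-231 genes was 0.18 as deposited and -0.01 after upper-quartile scaling, and the split of changed genes moved from 6149 higher and 3711 lower to 4736 and 4851. The counts of genes changed by at least 2-fold moved from 1671 higher and 1438 lower to 1137 and 1844 after upper-quartile scaling and 1392 and 1550 after quantile normalization. They were 875 and 685 at a pseudocount of 5, with 949 lower under the stricter filter and 917 higher after window centring. In camera at the preset correlation, 5 of the 35 splits of the 8 libraries passed at least the 17 lists of the true split, itself included.

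**Figure D2:**
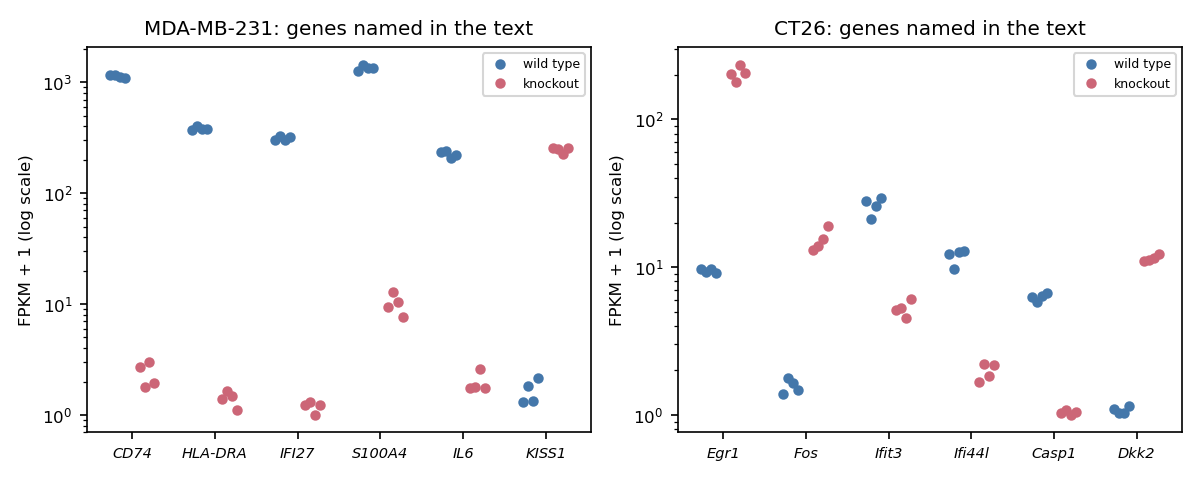
FPKM + 1 on a log axis for 6 genes named in the text per line, with 1 point per library (4 wild type, 4 knockout). The genes are among the largest rises and falls, which were picked so that wild type and knockout libraries do not overlap. CD74 had means of 1134 and 1.36 FPKM and Egr1 of 8.44 and 205 FPKM.

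In CT26 immediate early genes rose and interferon-stimulated and MHC class I genes fell, at adjusted p = 0.160, 0.370 and 0.160 with an estimated correlation, so none of the 3 lists passed camera that way. Egr1, a transcription factor gene induced by growth signals, went from 8.44 ± 0.337 to 205 ± 22.7 FPKM (SD, n = 4 per group), Fos from 0.576 ± 0.174 to 14.3 ± 2.59 FPKM and the MAP kinase phosphatase gene Dusp6 from 29.7 ± 2.93 to 106 ± 2.91 FPKM. The interferon-stimulated genes Ifit3 and Irf7 went from 24.99 ± 3.54 to 4.27 ± 0.643 FPKM and from 249.9 ± 17.4 to 86.3 ± 6.80 FPKM, and B2m, the light chain of MHC class I, from 1563 ± 51.9 to 757 ± 31.1 FPKM. In all, 6328 of 11342 genes (55.8%) changed in limma at an adjusted p below 0.05, 2534 higher and 3794 lower in the knockout, with 220 and 217 of them by at least 2-fold on the log2(FPKM + 1) scale. The 2-fold counts were 81 and 91 at a pseudocount of 5, and there were 342 higher at 0.1, 141 higher with the stricter filter and 140 lower after window centring.

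The 10 largest rises were Egr1 (log2 fold change 4.44, SE 0.08, adjusted p = 2.30e-08), the Wnt inhibitor gene Dkk2 (log2 fold change 3.42), Fos (3.27), the desmoglein gene Dsg4 (3.25), the semaphorin and VEGF co-receptor gene Nrp1 (2.71), Platr14 (2.71), the embryonic globin gene Hbb-bh1 (2.58), Klf2 (2.53), Ankrd37 (2.43) and Aldh7a1 (2.40). The 10 largest falls were Praf2 (log2 fold change -4.08, SE 0.11, adjusted p = 1.09e-07), the calsyntenin gene Clstn3 (log2 fold change -3.91), the phosphatase gene Ppef1 (-3.57), the inflammatory caspase gene Casp1 (-2.60), Ifi44l (-2.59), H2-T24 (-2.35), Klhl30 (-2.34), the schlafen gene Slfn2 (-2.33), Serpinb9b (-2.31) and Ifit3 (-2.30). Of the 11342 genes, 51.5% had groups that did not overlap, where chance gives 2.86%.

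All 24 tested immediate early genes of CT26 rose, with a median of 1.12 relative to all genes. Klf2 went from 2.504 ± 0.2996 to 19.2 ± 1.40 FPKM and the signalling inhibitor gene Spry2 from 7.92 ± 0.352 to 20.9 ± 0.891 FPKM. The camera adjusted p was 2.64e-16, and adjusted p = 0.160 with an estimated correlation. Of 17 p53 target genes 11 rose and 0 fell (camera adjusted p = 3.89e-05, and adjusted p = 0.160 with an estimated correlation). Named members were the cell cycle inhibitor gene Cdkn1a from 69.8 ± 3.08 to 157 ± 1.52 FPKM and Btg2 from 2.61 ± 0.245 to 14.1 ± 0.618 FPKM.

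Interferon-stimulated genes of CT26 fell in 31 of 38 members and rose in 5, with a median of -0.72 relative to all genes (camera adjusted p = 1.17e-06, and adjusted p = 0.370 with an estimated correlation). Ifi44 went from 208 ± 11.4 to 78.8 ± 2.86 FPKM, while Ifitm2 and Ifi27 went the other way, from 264 ± 5.30 to 455 ± 12.6 FPKM and from 76.5 ± 5.61 to 191 ± 8.21 FPKM. MHC class I genes fell in 16 of 20 members and rose in 1, with a median of -0.58 (camera adjusted p = 1.05e-04, and adjusted p = 0.160 with an estimated correlation). The heavy chain genes H2-K1 and H2-D1 went from 337 ± 5.66 to 211 ± 4.45 FPKM and from 665 ± 22.0 to 393 ± 19.6 FPKM, and H2-T23 from 42.9 ± 0.980 to 23.3 ± 0.850 FPKM. Interferon pathway components fell in 11 of 19 and rose in 4 (camera adjusted p = 0.458).

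Other cytokines, chemokines and growth factors of CT26 rose in 8 of 15 members and fell in 4 (camera adjusted p = 0.0185, and adjusted p = 0.339 with an estimated correlation). The EGF receptor ligand genes Ereg and Hbegf went from 8.42 ± 0.187 to 24.9 ± 0.858 FPKM and from 6.65 ± 0.398 to 24.3 ± 1.02 FPKM, Il11 from 1.32 ± 0.129 to 4.18 ± 0.336 FPKM and Csf1 from 154 ± 4.01 to 85.5 ± 2.06 FPKM. NF-kappaB targets rose in 6 of 15 and fell in 5 (camera adjusted p = 0.331), with Tnfaip2 and Nfkbiz at log2 fold changes of 0.91 and 0.47 and Nfkb2 and Ccl5 at -0.53 and -1.56. After centring on 20 Mb windows Nfkb2 was at -0.074 and no longer passed (adjusted p = 0.0976). Checkpoint genes rose in 2 of 8 and fell in 4 (camera adjusted p = 0.751), with Cd80 and Tnfsf9 at 0.67 and 0.38 and Lgals9 and Cd276 at -0.65 and -1.27. MHC class II genes rose in 3 of 6 and fell in 2 (camera adjusted p = 0.751). Cd74 went from 1.79 ± 0.318 to 0.463 ± 0.143 FPKM, and Rfxank, Rfx5 and Ifi30 had log2 fold changes of 1.04, 0.52 and -0.19. Rfx5 did not pass with no filter (adjusted p = 0.0511), nor did Ifi30 after upper-quartile scaling, at -0.096 (adjusted p = 0.0534).

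Glycolysis and hypoxia genes of CT26 rose in 18 of 26 members and fell in 2 (camera adjusted p = 1.05e-04, and adjusted p = 0.448 with an estimated correlation). Examples were the lactate exporter gene Slc16a3 at a log2 fold change of 0.93 and Pgk1 at 0.48. Respiratory chain genes fell in 17 of 27 and rose in 1 (camera adjusted p = 0.00146, and adjusted p = 0.448 with an estimated correlation). Among them were Atp5a1 at -0.60 and Ndufb8 at -0.64. After centring on 20 Mb windows their median relative to all genes moved from -0.18 to -0.10, with 11 lower and 3 higher (camera adjusted p = 0.0745). Unfolded protein and integrated stress response genes rose in 17 of 26 and fell in 5 (camera adjusted p = 0.00148, and adjusted p = 0.370 with an estimated correlation). The disulfide isomerase gene Pdia6 rose, at 0.99, and the stress transcription factor gene Ddit3 fell, at -0.90. PD-L1 trafficking and modification partners fell in 16 of 26 and rose in 0 (camera adjusted p = 0.0122, and adjusted p = 0.339 with an estimated correlation). Named members were the clathrin light chain gene Clta at -0.50 and Cmtm4 at -0.50. After upper-quartile scaling 14 of these partners fell and 3 rose. Neural and melanocyte markers rose in 4 of 5 and fell in 0 (camera adjusted p = 0.00256, and adjusted p = 0.339 with an estimated correlation). Examples were the neurofilament genes Nefm at 1.35 and Nefl at 1.75.

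The remaining CT26 lists with at least 5 tested members did not pass camera, with adjusted p from 0.165 to 0.926. Members rose and fell in 6 and 4 of 13 mesenchymal genes, 6 and 10 of 19 matrix and integrin genes, 10 and 7 of 20 TGF-beta and YAP targets, 5 and 10 of 24 G1/S genes, and 8 and 5 of 26 G2/M genes. The counts were 6 and 9 of 21 cholesterol genes, 3 and 5 of 14 fatty acid genes, 0 and 3 of 7 mitochondrially encoded genes, 2 and 6 of 13 heat shock genes, 5 and 8 of 19 NRF2 genes, 9 and 5 of 33 ribosomal protein genes, and 2 and 2 of 5 fibroblast and endothelial markers. After upper-quartile scaling cholesterol genes read 8 and 6, fatty acid genes 4 and 2, and ribosomal protein genes 21 and 3. Too few members were tested for camera among histone genes (2 of 3 rose, 0 fell), leukocyte markers (1 of 2 rose, 1 fell) and epithelial markers (1 of 3 rose, 1 fell). Adjusted over the list alone, 32 interferon-stimulated genes, 17 trafficking partners, 18 respiratory chain genes, 5 checkpoint genes and 8 heat shock genes fell. On the same basis 19 glycolysis genes rose and 3 fell, 7 cholesterol genes rose and 10 fell, 5 interferon pathway components rose, 3 fibroblast and endothelial markers rose, and the other lists kept their counts.

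The genes of CT26 chromosome 12 rose together in the knockout, 328 of 416 of them, with a median of 0.60 relative to all genes. Genes of chromosomes 14 and 8 rose (medians 0.33 and 0.30), and those of chromosome 1 fell, 471 of 658 of them (median -0.40). The medians of all other CT26 chromosomes lay within 0.07 of 0, although parts of chromosomes 5, 18 and 19 moved in opposite directions. In MDA-MB-231 the chromosome medians ran from -0.41 on X to 0.35 on chromosome 10. The parts before and after the middle did not move together on chromosomes 6 (-0.58 and 0.15), 16 (-0.01 and 0.56) and 18 (-0.11 and 0.27).

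**Figure D3:**
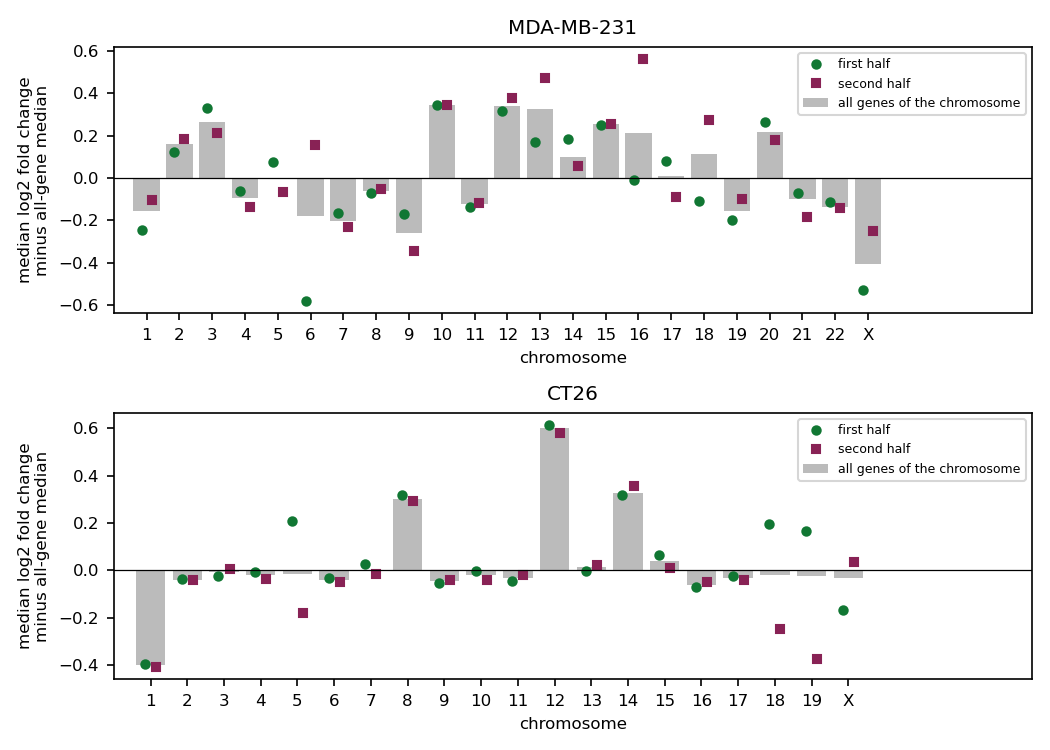
Median log2 fold change of the genes of each chromosome, relative to the median of all genes, for whole chromosomes (bars) and for the parts before and after the middle (points), in MDA-MB-231 (top) and CT26 (bottom). CT26 chromosome 12 has the largest median, 0.60.

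None of the CT26 lists passed camera with an estimated correlation, and 4 of the 35 splits of the 8 libraries passed at least the 10 lists of the true split at the preset one, itself included. After upper-quartile scaling the other cytokines, chemokines and growth factors had a camera adjusted p of 0.0505. It was 0.109 with no filter, where the list median fell to 0.014, 0.134 with the stricter filter and 0.0714 after window centring. The CT26 ribosomal protein genes passed after upper-quartile scaling (camera adjusted p = 0.00364), after window centring (1.13e-04, with 21 higher and 1 lower) and without chromosomes 1, 8, 12 and 14 (0.0379). The NRF2 genes passed as lower after window centring (camera adjusted p = 0.0129) and without those chromosomes (0.0154), and the mesenchymal genes as higher after window centring (0.0119). Mitochondrially encoded genes passed as lower with no filter (camera adjusted p = 0.0270), quantile normalization (0.0496) and the replicate block (0.0238), and G1/S and heat shock genes with no filter (0.0341 each). The split of changed genes was 40.04% higher as deposited and 53.9% higher after upper-quartile scaling, with 3316 higher and 2840 lower.

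**Figure D4:**
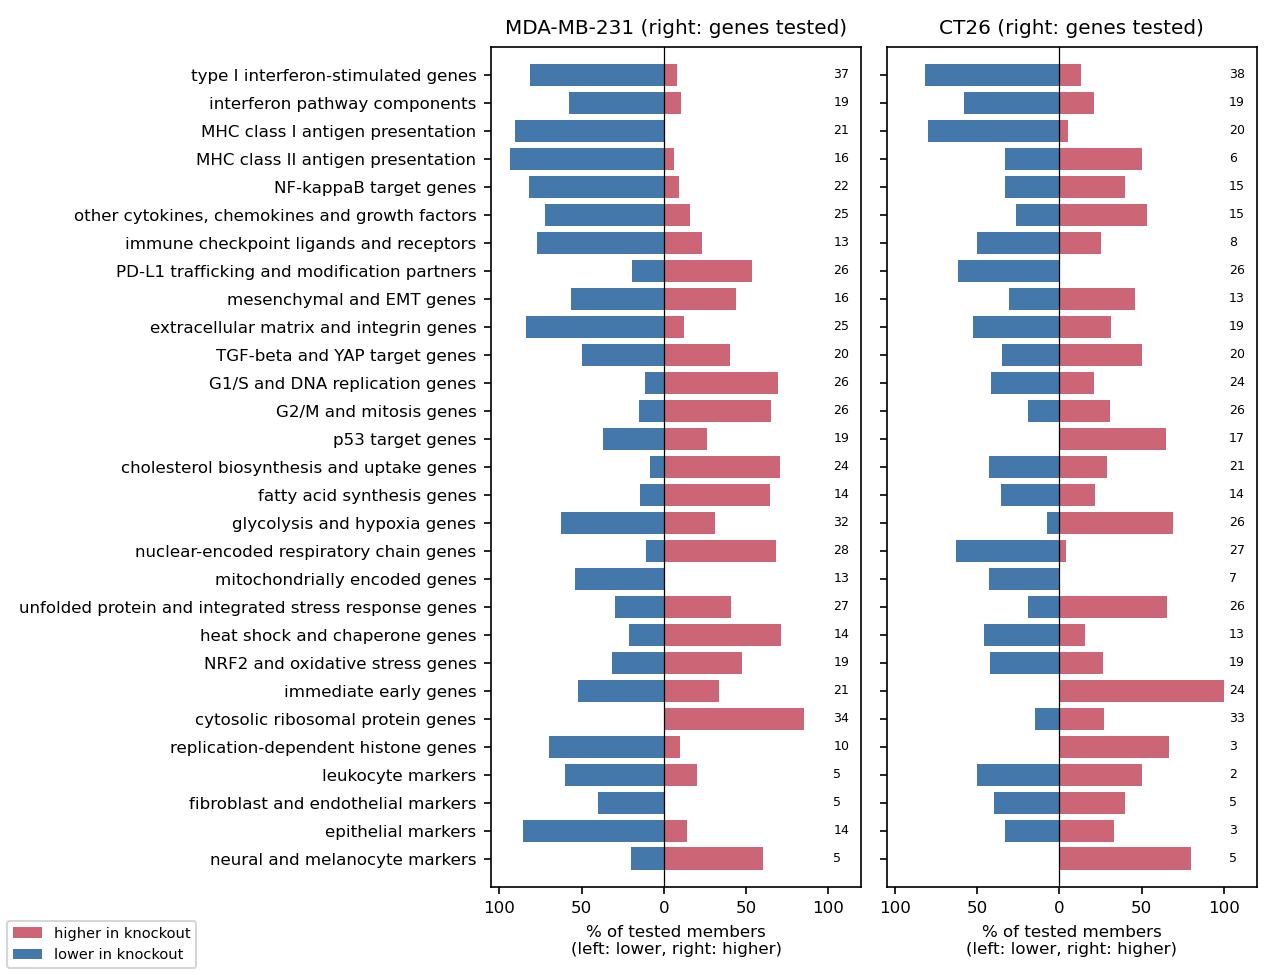
Percent of tested members of each of the 29 fixed lists that were lower (bars to the left) or higher (bars to the right) in the knockout at a limma adjusted p below 0.05, in MDA-MB-231 (left) and CT26 (right), with the number tested at the right. Interferon-stimulated genes fell in 30 of 37 members in MDA-MB-231 and 31 of 38 in CT26, and immediate early genes rose in 24 of 24 members in CT26 and 7 of 21 in MDA-MB-231.

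Over 8671 genes matched by symbol, genes called in both lines were ranked by the smaller of their 2 absolute log2 fold changes. The first 10 held 8 falls and 2 rises. The falls, in the order of MDA-MB-231, were in the guanylate-binding protein gene GBP2 (log2 fold change -4.42 in MDA-MB-231 and -1.60 in CT26), the nicotinamide methyltransferase gene NNMT (-4.29 and -1.97), SERPINB9, an inhibitor of granzyme B (-2.86 and -1.70), UBA7, the enzyme that activates ISG15 (-2.47 and -1.53), CCDC120 (-2.39 and -1.75), the matrix gene THBS1 (-2.27 and -1.67), IFIT3 (-1.95 and -2.30) and the chemokine gene CXCL10 (-1.64 and -1.92). FST, which encodes the activin antagonist follistatin (2.45 and 2.03), and DPY19L3 (1.64 and 1.85) rose in both. With a fold change of at least 2 in both lines, 42 genes were lower in both where independent lists would give 8.44 (one-sided Fisher's exact p = 2.73e-19), and 20 were higher in both where they would give 13.4 (p = 0.0436). In opposite directions, 28 were lower in MDA-MB-231 and higher in CT26 where independent lists would give 8.10, and 12 were the reverse where they would give 13.99. Without the fold limit the overlap was close to that of independent lists, with 784 lower in both against 751 (one-sided Fisher's exact p = 0.0424). For genes higher in both, 1000 were found against 970 (one-sided Fisher's exact p = 0.0642), and 2032 changed in opposite directions. These p-values moved with the processing. For higher and lower in both, the one-sided Fisher's exact p was 0.00859 and 4.83e-05 after upper-quartile scaling, 0.380 and 0.00214 after quantile normalization, and 0.0303 and 0.0518 with the replicate number as a block.

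Of the matched list members, 25 of 35 interferon-stimulated genes and 9 of 15 MHC class I genes fell in both lines, where the calls of each line alone would give 23.2 and 9.53. Across genes, which are not independent replicates, the fold changes of the lines had a Pearson r of 0.053 and a Spearman rho of 0.034. By the smaller of the 2 absolute changes, the first of the opposite changes were in ANXA8 (log2 fold change -3.58 in MDA-MB-231 and 2.23 in CT26), CDC42BPG (-2.64 and 2.22), FOS (-1.92 and 3.27), BSCL2 (-2.59 and 1.85) and FOXQ1 (-1.61 and 1.66).

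The responses of 1018 matched genes differed between lines by more than 2-fold in limma's treat. Of these, 380 were lower and 638 higher in MDA-MB-231 relative to CT26. The total was 857 after upper-quartile scaling and 859 after quantile normalization, and the split by direction was not counted there. As deposited, the median log2 fold change over all genes was 0.18 in MDA-MB-231 and -0.06 in CT26. Scaling alone can therefore move the split toward higher in MDA-MB-231. Immediate early genes (median difference -1.65), NF-kappaB targets (-2.34), glycolysis and hypoxia genes (-1.66) and interferon-stimulated genes (-0.78) were lower in MDA-MB-231 relative to CT26, by a camera test of the difference. In that order, the lists had adjusted p = 0.0161, 0.00174, 0.0415 and 0.0415 with an estimated correlation. Of 24 lists, 18 differed at the preset correlation and 9 with an estimated one. Pairing by symbol is not an orthology table, and genes with no partner of the same symbol, such as most HLA and H2 genes, were not compared.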

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

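The tests of explanations and the counts of other splits in this part were chosen after the results they concern had been seen, as was the set of named genes it covers. The bounds for window centring and for depth were also loosened after their values were known, and under the first ones class I genes of CT26 against chromosome shifts and interferon-stimulated genes of MDA-MB-231 against depth had been left open. Other splits of the libraries gave far fewer changed genes. The true split of MDA-MB-231 changed 9860 genes, and the highest of the other 34 splits changed 4, so 1 of 35 splits reached the true count. For CT26 the true count was 6328, the highest other was 3, and again 1 of 35 splits reached it. Every other split mixes the genotypes, so a chance difference between cultures was not tested. A chance division of the libraries is argued against for these counts only by rank, at the smallest share that 35 splits allow. Splits that mix the genotypes put any genotype difference into the spread within groups. Their low counts therefore say nothing about how many of the calls are false. For the number of lists past camera at the preset correlation a chance division cannot be excluded, and these splits cannot decide it. In MDA-MB-231 5 of 35 splits reached the 17 lists, with the highest other split at 17. In CT26 4 of 35 reached the 10 lists, with the highest other split at 11. A split with more of 1 genotype on 1 side keeps part of the genotype difference, so its lists need not be chance. Over 100 splits of both lines together, 1 reached the 1018 genes that differ between lines, with the highest other at 459. A chance division of the libraries is argued against for that count too, with the same limit. For the 1784 genes changed in the same direction 1 of the 100 splits reached the true count, with the highest other at 0, but the other splits change so few genes in each line that the count says nothing about sharing. Set against independent lists, the 1000 genes higher and 784 lower in both compare with 970 and 751. Of the 100, 3 kept the true split in 1 line.

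The first pattern was a shift of chromosomes or large parts of them, with a median log2 fold change relative to all genes in CT26 of 0.60 on chromosome 12, 0.33 on 14, 0.30 on 8 and -0.40 on 1, and in MDA-MB-231 from -0.41 on X to 0.35 on 10. Chance placement of changed genes is argued against in both lines, since permuting genes over chromosomes gave as wide a spread with p = 0.001 in each, the smallest that 1000 permutations can give, and GC content and transcript length are argued against in MDA-MB-231, since correcting for them left 95.2% of the spread of 20 Mb window medians. A copy number difference between the cultures may underlie the shifts in MDA-MB-231: the medians of the parts before and after the middle of each chromosome correlated with r = 0.545 (permutation p = 0.007), with rho 0.669 (permutation p = 7e-04) and with r = 0.661 without the 2 farthest chromosomes. In CT26 r was 0.664 with permutation p = 0.002, but rho was 0.350 with permutation p = 0.1. Without the 2 farthest chromosomes, which are the shifted 12 and 1, r fell to 0.219, so this test cannot decide there. On the shifted CT26 chromosomes both parts moved alike: 12 (0.61 and 0.58), 14 (0.32 and 0.35), 8 (0.32 and 0.29) and 1 (-0.40 and -0.41). That goes with a copy number difference but does not show it, and regional regulation was not tested. Parts of 5 (0.21 and -0.18), 18 (0.20 and -0.25) and 19 (0.16 and -0.37) moved in opposite directions. The breadth in MDA-MB-231 has a further open explanation, cells of another origin: 52 genes were at 10 FPKM or more in every library of 1 genotype and 0.5 or less in every library of the other, against 0 in CT26, whereas both genotypes lacked MTAP and CDKN2B, at 0.0205 FPKM or less, which goes with a shared origin but does not show it, and origin, clone and knockout cannot be told apart because each follows the genotype.

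The second pattern was the fall of interferon-stimulated and MHC class I genes in both lines, although in CT26 they had adjusted p = 0.370 and 0.160 with an estimated correlation. Chromosome shifts are argued against as the whole cause for the interferon-stimulated genes, whose median after centring on 20 Mb windows was -1.53 in MDA-MB-231 and -0.67 in CT26, and for class I in MDA-MB-231 at -1.30. They are argued against in the same way for class I in CT26, where the median was -0.58 before centring and -0.63 after it. Its bootstrap interval, from -0.81 to -0.19, resampled the genes as if they were independent and may be too narrow. The 11 class I members of CT26 with a mean of 50 FPKM or more had a smaller fall before centring, with a median of -0.29. Of these, 10 lay below the median of all genes. The lower depth of the MDA-MB-231 knockout is argued against for class I, where all 14 members with a mean of 50 FPKM or more lay below the median of all genes, with a median of -1.10, and for the interferon-stimulated genes, where 6 of 7 such members lay below it, with a median of -3.46. The mean of 50 FPKM was taken over both genotypes, so members such as IFI27 and BST2 reach it only through the wild type. The medians of the MDA-MB-231 members picked this way can therefore overstate the fall. The loss of PD-L1 and other differences between the cultures stay open, and neither was tested.

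The third pattern was the rise of the immediate early genes in CT26, where all 24 were higher in every knockout library than in every wild type library, although the list had adjusted p = 0.160 with an estimated correlation. Heat stress at harvest is argued against as the whole cause. The tested heat-inducible genes Hspa1b, Dnajb1, Hsph1 and Bag3 had a median of -0.10 relative to all genes, and the highest, Dnajb1, was at 0.41. Other proteotoxic stress stays open. Unfolded protein and integrated stress response genes rose in 17 of 26 members and fell in 5 (camera adjusted p = 0.00148, and adjusted p = 0.370 with an estimated correlation). Growth or handling at harvest may have differed between the cultures, and this cannot be told apart from the knockout, since each follows the genotype and the 24 of 24 would follow from either.

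In 21 of 304 groups of 4 libraries tested, where chance gives about 1 in 20, a single library lay far from the other 3 for a named gene. Over all members the naming rule allows, it was 38 of 560. In MDA-MB-231 knockout replicate 3 read 0.0864 FPKM for HLA-DRB1, 0.311 for HLA-DPA1, 0.0653 for HLA-DPB1, 1.59 for IL6 and 1.04 for ANXA8, each above the others. Knockout replicate 2 read 36.5 FPKM for CD96, 916 for COX4I1 and 0 for SAA2, and knockout replicate 4 read 125 for FKBP10 and 6.12 for HIST1H2BD. In the wild type, replicate 4 read 0.162 FPKM for CD96 and 118 for EBP, replicate 1 read 49.6 for CXCL1, replicate 3 read 22.3 for EGLN3, and replicate 2 read 75.2 for BSCL2. In CT26 the knockout libraries that stood apart were replicate 1 for Ppef1 at 0.00934 FPKM, replicate 2 for Thbs1 at 7.10, replicate 3 for Hbb-bh1 at 4.36 and replicate 4 for Cmtm4 at 6.52, and the wild type ones were replicate 2 for Ifi44l at 8.73 and replicate 3 for Pdia6 at 137.

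Of 81 named genes tested in both lines, 48 had responses that differed by more than 2-fold in limma's treat, and over all members the naming rule allows it was 73 of 171. Over all matched genes it was 1018 of 8671. The named genes were picked from these data for large changes or small p, so a higher share was built in. The values are the log2 fold change in MDA-MB-231 minus that in CT26. The widest differences toward lower in MDA-MB-231 were in IFI27 (-9.36), CD74 (-8.01), S100A4 (-7.21), ANXA8 (-5.80), BST2 (-5.74), EGR1 (-5.48), CXCL1 (-5.30), FOS (-5.20), CDC42BPG (-4.85), CDKN1A (-4.67), BSCL2 (-4.44), COL5A1 (-3.99) and KRT7 (-3.79). Smaller ones were in NRP1 (-3.59), CSF1 (-3.51), FOXQ1 (-3.27), ISG15 (-3.12), P4HA2 (-3.12), SLC16A3 (-3.02), OASL (-2.95), GBP2 (-2.82), SOCS1 (-2.68), TNFAIP2 (-2.43), TNFSF9 (-2.34), NNMT (-2.32) and IER3 (-2.29). The rest were in ANKRD37 (-2.001), NFKBIZ (-1.71), MT-ND6 (-1.68), EREG (-1.64), IER5 (-1.54), PGK1 (-1.51), NFKB2 (-1.47), KLF2 (-1.43), TAPBP (-1.40), SPRY2 (-1.26), HBEGF (-1.26) and CD47 (-1.23). Responses higher in MDA-MB-231 were those of FKBP10 (6.27), PHGDH (5.05), CLSTN3 (3.95), SCD (3.51), PRAF2 (2.89), FADS2 (2.22), IL11 (1.83), SREBF2 (1.67), NDUFA9 (1.40) and RPL4 (1.29).

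Of the lists, 9 differed between lines by camera at both the preset and the estimated correlation. Only members matched by symbol entered. For MHC class II these were 6, with medians relative to all genes of -0.91 in MDA-MB-231 and 0.20 in CT26. All 16 tested class II members of MDA-MB-231 had a median of -4.88. The median difference, MDA-MB-231 minus CT26, was -0.78 for interferon-stimulated genes, -0.34 for interferon pathway components, -1.11 for MHC class II, -2.34 for NF-kappaB targets, -1.50 for other cytokines, -0.92 for matrix and integrin genes, -0.55 for p53 targets, -1.66 for glycolysis and hypoxia genes and -1.65 for immediate early genes.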

How the results depend on the processing

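Centring on 20 Mb windows, leaving out chromosomes and the restriction to protein-coding genes were chosen after the chromosome shifts were seen. Over all alternatives the counts of changed genes ran from 7755 to 11115 in MDA-MB-231 and from 4809 to 6354 in CT26. Without 1 library at a time they ran from 9338 to 9602 in MDA-MB-231 and from 5773 to 6008 in CT26, and the log2 fold change of CD274 ran from -0.28 to -0.10 and that of Cd274 from -0.70 to -0.63. Cd274 read -0.38 with window centring, -1.27 at a pseudocount of 0.1 and -0.21 at 5, and its adjusted p ran from 1.08e-04 to 0.00490 over the alternatives that tested it. The stricter filter removed it and gives no value. Of the 9860 and 6328 calls, 9412 and 5781 were called again in the same direction with the replicate number as a block. After window centring 7758 and 3978 were, and 164 and 145 were called in the opposite direction. The planned count models, edgeR and DESeq2, were not run because no counts were used. Same-numbered libraries deviated together by correlations of only -0.037 to 0.004 in MDA-MB-231, so the numbers do not pair them there. In CT26 the correlations were 0.027 to 0.078 and all 4 correlated best with their own number, so a weak pairing cannot be excluded. The cause of the following changes was not tested, except where fewer genes or a fold limit shows it.

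With upper-quartile scaling CD274 read -0.40 (adjusted p = 0.0157), with quantile normalization -0.32 (0.0425) and with window centring -0.41 (0.0191), and all passed the threshold. Counts of genes changed by at least 2-fold moved with the pseudocount. At 5 they were 875 higher and 685 lower in MDA-MB-231 and 81 and 91 in CT26, and at 0.1 CT26 had 342 higher. The stricter filter left 949 lower in MDA-MB-231 and 141 higher in CT26, where fewer genes were tested. Window centring left 917 higher in MDA-MB-231 and 140 lower in CT26, and without chromosomes 1, 8, 12 and 14 CT26 had 1598 genes higher. Lists past camera with an estimated correlation were 7 lower and 0 higher in MDA-MB-231, and 0 and 0 in CT26. At the preset correlation, 8 lists were higher in MDA-MB-231 and 7 lower in CT26 with no filter, and 2 were higher in MDA-MB-231 with quantile normalization. With a fold limit in both lines 20 genes were higher, 42 lower and 40 opposite. Without the 2-fold margin 6265 genes differed between lines.

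The direction given by camera reversed for some lists, mostly with medians near 0 relative to all genes. With no filter the medians were 0.052 for stress response and -0.012 for NRF2 genes in MDA-MB-231 and -0.075 for cholesterol genes in CT26. With quantile normalization they were -0.083 for trafficking partners in MDA-MB-231, and -0.061 for matrix genes and 0.0063 for fatty acid genes in CT26. With the stricter filter matrix genes read -0.071 and fatty acid genes -0.0056 in CT26. Fatty acid genes of CT26 also read -0.019 with upper-quartile scaling, 0.042 with window centring and 0.041 without the 4 chromosomes. Without 1 library at a time they ran from -0.050 to 0.013, and reversed only without knockout replicate 4. Window centring gave 0.14 for mitochondrially encoded genes of MDA-MB-231, where the window is the mitochondrial genome itself. It also reversed single genes, with log2 fold changes of -0.045 for KIF11 and -0.025 for NQO1 in MDA-MB-231, and of 0.22 for Rpl7, 0.13 for Rps14 and 0.24 for Pdgfrb in CT26, of which Rpl7 and Pdgfrb passed the threshold. Among single genes the naming rule allows, 15 values over all alternatives kept their direction and lost the threshold, 8 of them after window centring. Among lists that kept their direction, 33 values lost it and 17 gained it. Reversed values are not in these counts. Depth limits mostly the low genes of the MDA-MB-231 knockout.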

Other observations

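The gene families of this part were chosen after the data were seen, by grouping genes of the same symbol stem with at least 6 tested members, as were the genes MTAP, CDKN2B and CDKN2A. In MDA-MB-231 the CXC chemokine genes fell in 7 of 7 members (median -3.52 relative to all genes), cystatin genes (stem CST) in 6 of 6 (-4.40), butyrophilin genes (BTN) in 6 of 6 (-1.57), claudin genes in 7 of 9 with 2 higher (-1.41), and keratin genes in 11 of 16 with 4 higher (-1.01). Large-subunit mitochondrial ribosome genes (MRPL) rose in 40 of 50 members and fell in 3 (0.39), translation initiation factor genes (EIF) in 46 of 65 with 4 lower (0.42), the UTP genes of ribosome assembly in 11 of 11 (0.82), and chaperonin genes (CCT) in 11 of 12 with 0 lower (0.43). These passed camera at the preset correlation over 311 stems, with adjusted p from 1.69e-04 to 0.0278, and did not pass with an estimated one, where the smallest was adjusted p = 0.636. After window centring they passed as well, with the median of butyrophilin genes at -0.99 and that of chaperonin genes at 0.68.

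In CT26 none of 237 stems passed camera, with a smallest adjusted p = 0.183. After window centring the stem RPL, of 67 genes, passed as higher at the preset correlation (camera adjusted p = 7.58e-04, median 0.17 relative to all genes). An estimated correlation was not tried with window centring. At both the MTAP and the CDKN2B gene of MDA-MB-231, neighbours on chromosome 9 known to be deleted in this line, no library of either genotype exceeded 0.0205 FPKM. Their neighbour CDKN2A reached 0.394 FPKM in the wild type and 0.733 in the knockout.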
